A study of Mus musculus with 16 samples.

How the data were processed

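Bulk RNA was sequenced from 4 mononuclear phagocyte populations of C57BL/6 mice aged 8 to 10 weeks, with 4 libraries per population. Per the labels, cornea macrophages were sorted as CD45+CD11b+CD64+F4/80+ cells, retinal microglia and brain microglia as CD45+CD11b+ cells, and bone marrow monocytes as CD45+CD11b+CD115+Ly6C+ cells. Each cornea and each retinal sample came from 10 pooled mice. The sample descriptions of the 8 brain and bone marrow libraries name retinal microglia, against the title, source and population of the same samples. These 8 libraries were grouped by title, source and population, and their pool size was treated as unknown. The cornea was digested with collagenase D at 37 °C under shaking, whereas the retina was dissociated mechanically in cold buffer. The text on tissue handling ends before any brain or bone marrow part. The extraction text describes a brainstem region of another mouse line and a stranded mRNA library kit, so kit and strand were treated as uncertain.

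The deposited file holds raw read counts per gene for 16 libraries, whole numbers without normalization, over 45664 gene entries. It also holds a gene length column, of unit other (bases), per the file headers; lengths were not used here. The authors name CASAVA 1.8.2, Subread, featureCounts, limma and genome build GRCm38.p4 without giving their order. Versions of Subread, featureCounts and limma, the annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. The column headers place 8 libraries in lane 2 and 8 in lane 3 of the sequencer. Lane 2 held all 4 retinal libraries, 3 cornea libraries and 1 bone marrow library. Lane 3 held all 4 brain libraries, 1 cornea library and 3 bone marrow libraries. Titles of 3 libraries (cornea 1, retina 1 and retina 3) lack a letter b that the other titles carry, and its meaning is not given in the sources used here. Each of these 3 shares its title number with a library of the same population that has the letter (cornea 1 and 2, retina 1 and 2, retina 3 and 4). Whether such libraries came from separate samples is not given either; they were counted as separate libraries, so n = 4 may overstate the number of separate samples of cornea and retina. Replicate numbers follow the order of deposition.

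Symbols of 27 gene entries had been turned into dates, taking at most 0.223% of a library's counts. They were kept apart from other genes, and 2 symbols on 4 entries were kept as separate entries. A further 16739 entries had a count of 0 in all libraries. GENCODE vM21, on build GRCm38, held 91.8% of the symbols and supplied the coordinates. Total counts per library ranged from 8.68 to 21.76 M (mega-counts). No 2 libraries of a population were copies of each other: over 24 pairs, the chi-square per degree of freedom between counts lay between 12.15 and 104.79. The pairs with a shared title number had 24.26, 29.4 and 104.79, which excludes copied counts and leaves a shared source of cells open.

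Genes were filtered with filterByExpr by population (minimum count of 10), which left 15754 genes. All 16 libraries were fitted together in edgeR 4.0.16 under R 4.3.3, with TMM scaling factors and population as the only term. Each of the 6 pairs of populations was compared with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested genes. A gene was called changed at an adjusted p under 0.05, and the number changed at least 2-fold was counted beside it. Gene levels are CPM, counts scaled by TMM to the effective library size, given as mean ± SD with n = 4 libraries per population. Log2 fold changes are those of the edgeR fit. The standard error (SE), where given, is the absolute log2 fold change divided by the square root of the test's F statistic. It therefore adds nothing beyond the fold change and its test. A signature gene of a population had an adjusted p under 0.05 and a log2 fold change of at least 1 against each of the other 3 populations.

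For genes with a count of 0 in all 4 libraries of a population, folds are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of pooled CPM is given with its exact 95% counting interval. Intervals and floors cover counting error only, since reads carried no molecular identifiers. For each comparison, genes whose 4 libraries of 1 population all lay above the 4 of the other were counted, which chance gives for 2.86% of genes. Spearman correlations and principal components were computed across genes on log2 CPM with a prior count of 2. Correlations across genes describe likeness of libraries, and genes are not independent replicates.

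The comparisons, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. The 31 lists hold 393 genes. Lists of cell programmes covered the sort markers, homeostatic microglia, disease-associated microglia, border and tissue macrophages, classical monocytes, MHC class II presentation, the interferon response, inflammatory cytokines and chemokines, immediate-early and dissociation genes, the cell cycle, complement, lysosome and phagocytosis, the TGF-beta pathway, matrix remodelling and repair, myeloid transcription factors, and lipid and cholesterol genes. Lists of other cells covered photoreceptors, Müller and astroglia, neurons, oligodendrocytes, corneal epithelium, stromal keratocytes and fibroblasts, endothelium, pigmented cells, neutrophils and granulocyte precursors, lymphocytes and NK cells, dendritic cells, mast cells and basophils, and erythroid cells. Sex-linked genes and mitochondrial transcripts served as checks. Each list was also tested with limma's fry (limma 3.58.1), adjusted over 168 tests of lists with at least 2 measured members. Fry's p tests whether a list's genes move, on balance, in 1 direction, and compares them with no other genes.

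Named genes were chosen by rule among called genes with a mean of at least 20 CPM in the higher population and no overlap between libraries, leaving out unnamed gene models. The rule took the 8 largest and 8 smallest log2 fold changes per comparison and the 6 genes with the largest smallest log2 fold change per signature. Changes called largest or leading below are so among genes that passed these limits. For each list described, it took up to 4 measured members with the largest absolute log2 fold change and any member that went against the majority. Some genes that this rule took are not reported here. Named outside this rule, after their values were seen, were Apoe, P2ry12, Mrc1, Ccr2, Sall1, Tmem119, Trem2, Ccl24, Tgm2, Csf1r, Jun, Fos, Pf4 and Zbp1, each in at least 1 comparison, and Cd79b, Mbp, Slc1a3 and Pecam1.

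Alternatives covered DESeq2 size factors, total counts only, no filter, a filter of 5 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, at least 2-fold changes or a log2 fold change of at least 2 for signatures, the 8 libraries of each pair alone, marker and mitochondrial genes left out, leaving out each library in turn, and leaving out the 3 libraries without the letter b. Brain and bone marrow were also fitted with a block of 3 levels from ranges shared by their titles. Chosen after seeing the data were the lane as a term, fits within 1 lane, and leaving out genes that tracked photoreceptor transcripts. Total counts only, without scaling factors, moved the median log2 fold change of all genes by 0.12 for retinal against brain microglia and for retinal microglia against monocytes. The same setting moved that median by -0.79, -0.67 and -0.67 for cornea macrophages against retinal microglia, brain microglia and monocytes. Changes are given relative to the TMM scaling. Figures were drawn with matplotlib 3.10.9 and NumPy 2.4.6 under Python 3.11.15.

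The fit was tested on simulated data with 67 or 66 changed genes at each of 3 fold sizes per comparison. Every other gene had the same mean level in all populations, and the changed genes were drawn from those with higher mean counts. At a simulated fold of 4, edgeR recovered 77.6% (brain against bone marrow) to 91% (cornea against brain) of them, and at 16-fold 93.9% to 100%. At 2-fold it recovered 32.8% to 56.7%, so changes of this size were often missed in this setting. A line of 80% at 4-fold had been set for this check and was missed by brain against bone marrow; the simulation was kept as it came. False calls made up 1.4% to 5.8% of edgeR's calls, 13.8% to 20.3% of DESeq2's and 2.7% to 6.8% of limma-voom's. The real comparisons called 10.5% to 66.8% of genes changed, far more than were simulated, so these shares need not carry over to them.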

Results

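The data are total RNA read counts of 4 sorted mouse populations: macrophages of the cornea, microglia of the retina, microglia of the brain, and Ly6C+ monocytes of the bone marrow. The study's design text speaks of mRNA signatures of these populations, so each pair was compared and each population's own genes were sought. Each population had 4 libraries. Total counts, in mega-counts (M), averaged 17.64 ± 3.8 M (SD, n = 4) for cornea macrophages, 15.97 ± 3.87 M for retinal microglia, 10.34 ± 1.81 M for brain microglia and 13.1 ± 5.39 M for monocytes. Single libraries held 12.57, 17.78, 18.47 and 21.76 M counts (cornea), 10.71, 17.23, 16.01 and 19.94 M (retina), 10.4, 8.68, 9.45 and 12.85 M (brain), and 20.71, 8.91, 9.66 and 13.1 M (bone marrow).

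On average, libraries of a population resembled each other more than those of any other population. Mean Spearman correlations across genes were 0.963 among cornea libraries, 0.963 among retinal, 0.98 among brain and 0.982 among monocyte libraries. Retinal and brain microglia came close to this, with a mean of 0.939 between them, and single pairs overlapped: the lowest correlation of 2 retinal libraries was 0.941 and the highest of a retinal with a brain library 0.951. The other 5 pairs of populations averaged 0.707 to 0.756. The first principal component held 47.1% of the variance and set both microglia populations apart from cornea macrophages and monocytes. The second component (33%) parted cornea macrophages from monocytes, and the third (6.3%) parted retinal from brain microglia.

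**Figure D1:**
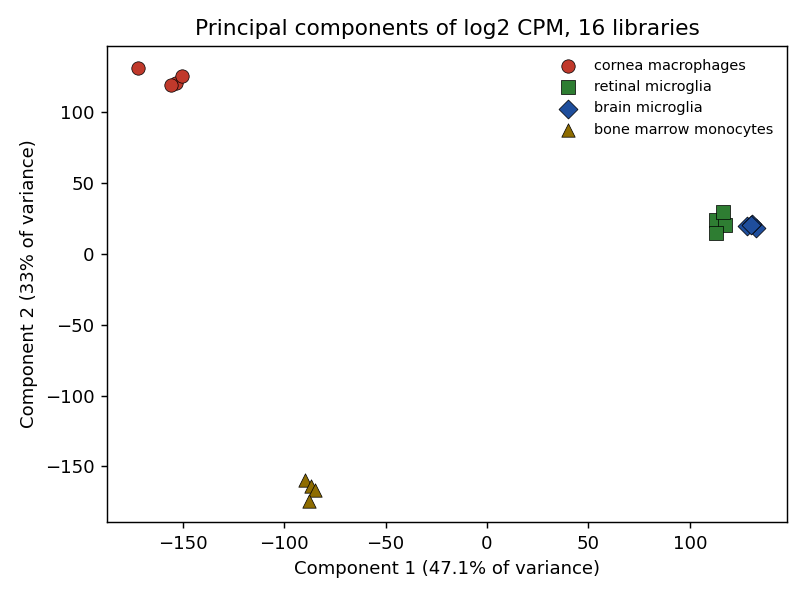
Principal components 1 (47.1% of variance) and 2 (33% of variance) of log2 CPM over the tested genes, with 1 point per library coloured by population. Retinal and brain microglia lie close together, away from cornea macrophages and bone marrow monocytes.

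The sort markers differed in level among the populations. Csf1r, the receptor of the macrophage growth factor, had 11975 ± 1366 CPM in brain microglia, 8247 ± 971 in retinal microglia, 2800 ± 234 in cornea macrophages and 1540 ± 91.3 in monocytes. Cx3cr1, the fractalkine receptor, had 5332 ± 811 and 3573 ± 623 CPM in brain and retinal microglia, 442 ± 137 in monocytes and 99.6 ± 11 in cornea macrophages. Adgre1, which encodes F4/80, was highest in cornea macrophages (2515 ± 106 CPM), followed by brain microglia (948 ± 101), retinal microglia (506 ± 86.5) and monocytes (432 ± 124). Fcgr1, which encodes CD64, had 353 ± 48.2 and 323 ± 37.7 CPM in retinal and brain microglia, 129 ± 5.38 in monocytes and 71.3 ± 10.2 in cornea macrophages. Ptprc (CD45) had 695 ± 75.5, 559.7 ± 85.5, 396 ± 29.9 and 1492 ± 232 CPM in cornea, retina, brain and bone marrow, and Itgam (CD11b) had 645 ± 94, 870.1 ± 262, 1393 ± 181 and 863 ± 41.9 CPM in the same order. Ly6c2 and Ly6c1, which encode Ly6C, reached 2464 ± 141 and 18.3 ± 5.9 CPM in monocytes, against at most 0.286 ± 0.232 and 0.0639 ± 0.128 CPM elsewhere. Xist, expressed from the inactive X chromosome, had 804 to 4641 counts in every library, and no Y-linked gene of the list (Ddx3y, Kdm5d, Eif2s3y, Uty) exceeded 3 counts.

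Markers of other cells were measured in each sort. Retinal microglia held rod photoreceptor transcripts such as rod transducin (Gnat1, 605 ± 434 CPM). Cornea macrophages held keratocyte transcripts such as decorin (Dcn, 774 ± 237 CPM) and epithelial transcripts such as Aldh3a1 (315 ± 187 CPM) and the corneal keratin Krt12 (195 ± 193 CPM). Monocytes held granulocyte transcripts such as Ngp (423 ± 482 CPM) and Mpo (378 ± 146 CPM) and haemoglobin transcripts such as Hbb-bs (529 ± 443 CPM).

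**Figure D2:**
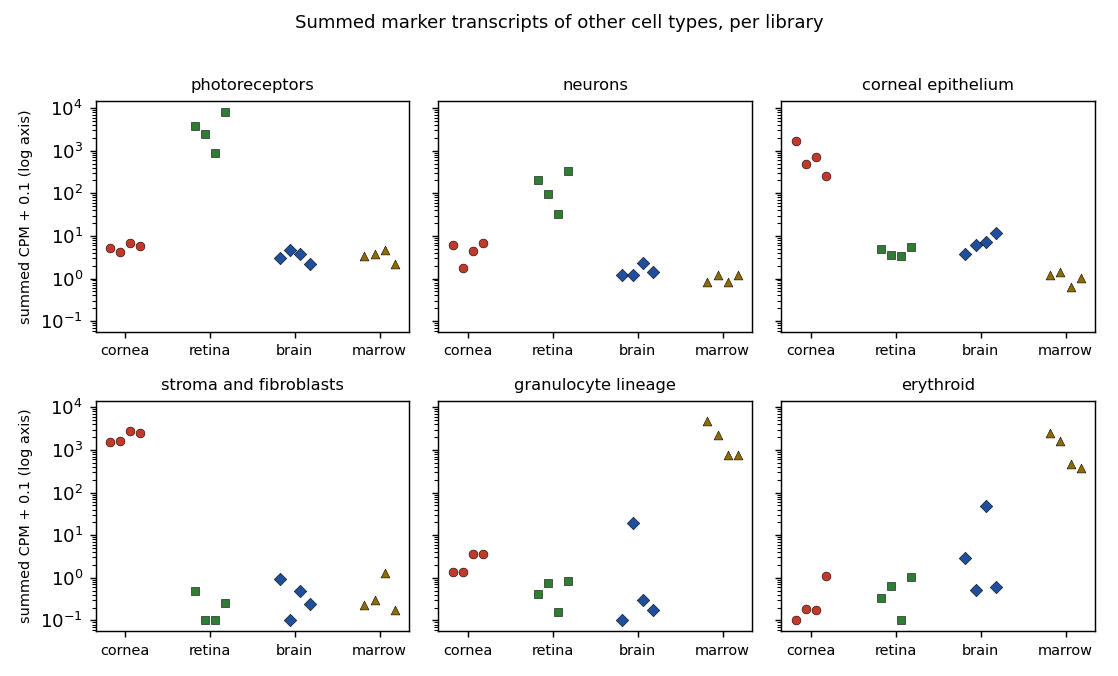
Summed CPM plus 0.1 (log axis) of the photoreceptor, neuron, corneal epithelium, stromal, granulocyte and erythroid lists, with 1 point per library in each of the 4 populations. Photoreceptor and neuronal sums are highest in retinal libraries, corneal and stromal sums in cornea libraries, and granulocyte and erythroid sums in bone marrow libraries.

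The comparison of retinal with brain microglia asks what sets microglia of the retina apart. Retinal microglia held more Axl, a receptor for dying cells (255 ± 66.6 against 19.3 ± 8.19 CPM), more Clec7a, the beta-glucan receptor (290.4 ± 61.8 against 22.4 ± 2.3 CPM), and more Gpnmb (55.1 ± 19 against 0.442 ± 0.544 CPM). Apoe, a lipid carrier, rose from 523 ± 34.5 CPM in brain to 2531 ± 843 CPM in retinal microglia, with a log2 fold change of 2.27 (SE 0.23; adjusted p = 4.62e-06). In the opposite direction, Fcrls, an Fc receptor-like gene of microglia, fell from 3453 ± 520.3 to 591 ± 153 CPM (-2.55 on the log2 scale, SE 0.22; adjusted p = 1.35e-06). The purinergic receptor P2ry12 fell from 13785 ± 519 to 7527 ± 1012 CPM. On build GRCm38, these genes lie on chromosome 3 (Fcrls, 87250758 to 87263738; P2ry12, 59216272 to 59262871), chromosome 6 (Clec7a, 129461591 to 129472779) and chromosome 7 (Apoe, 19696109 to 19699188).

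Of 15754 genes tested with edgeR's quasi-likelihood test, 1662 changed, 1095 higher and 567 lower in retinal microglia, and 1008 changed at least 2-fold. With total counts only, 1643 changed, 1353 higher and 290 lower. The 4 retinal libraries did not overlap the 4 brain libraries for 2854 of the 15754 genes, where chance gives 2.86%. All retinal libraries were in lane 2 and all brain libraries in lane 3. With the lane as a term, estimated from the cornea and bone marrow libraries on both lanes, 463 genes changed (316 higher and 147 lower), of which 394 were among the 1662.

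Among homeostatic microglia genes, 0 of 19 measured members were higher and 6 lower (0 and 10 adjusted over the list alone) (fry, adjusted p = 1.84e-06). Besides Fcrls, the uroplakin Upk1b fell from 126 ± 23.9 to 21.2 ± 6.66 CPM and the crystallin Crybb1 from 124 ± 26.7 to 48.4 ± 14 CPM. Adamts1 had 24.6 ± 10.0 CPM in retinal and 12.1 ± 3.99 CPM in brain microglia and did not pass the test. Levels of Sall1 and Tmem119 were 539.9 ± 134 and 2836 ± 456 CPM in retinal and 688 ± 66.2 and 3774 ± 364 CPM in brain microglia, and neither passed the test. Of the disease-associated microglia genes, 10 of 18 measured members were higher and 1 lower (12 and 1 adjusted over the list alone) (fry, adjusted p = 1.25e-06). Lgals3, which encodes galectin-3, rose from 2.69 ± 0.811 to 30.9 ± 11.4 CPM, and Ank was lower (39.7 ± 8.32 against 62.9 ± 13.1 CPM). The call of Ank ended without any 1 of retinal replicates 1, 3 and 4 and brain replicates 3 and 4 (log2 fold changes of -0.65 to -0.53). Trem2 had 984 ± 244 and 963 ± 101 CPM in retinal and brain microglia and did not pass the test.

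Interferon response genes rose together: 16 of 18 measured members were higher and 0 lower (17 and 0 adjusted over the list alone) (fry, adjusted p = 1.71e-06). Ifi204 rose from 7.89 ± 1.61 to 51 ± 6.86 CPM, Mx1 from 5.03 ± 3.72 to 29.1 ± 5.34, Rsad2 from 2.05 ± 1.58 to 12.2 ± 4.77 and Ifi44 from 0.0907 ± 0.181 to 1.35 ± 0.862. Cell cycle genes also rose: 13 of 16 measured members were higher and 0 lower (13 and 0 adjusted over the list alone) (fry, adjusted p = 1.25e-06). Their levels stayed low, with Top2a at 22.6 ± 4.23 against 1.15 ± 1.77 CPM, Rrm2 at 14.4 ± 5.97 against 0.746 ± 1.18, Plk1 at 6.56 ± 2.77 against 0.186 ± 0.141 and Birc5 at 4.98 ± 1.97 against 0.274 ± 0.285. In the MHC class II list, 4 of 13 measured members were higher and 1 lower (5 and 2 adjusted over the list alone). The class II chains H2-Aa (26.2 ± 12.4 against 1.37 ± 1.22 CPM), H2-Eb1 (15 ± 5.1 against 1.18 ± 0.617) and H2-Ab1 (72.9 ± 16.5 against 10.1 ± 0.868) rose, while the co-stimulatory gene Cd86 fell from 544 ± 94.5 to 341 ± 40.0 CPM. Cd40 had 1.24 ± 1.69 and 0.18 ± 0.215 CPM and did not pass the test. Of the dendritic cell genes, 1 of 8 measured members were higher and 0 lower (1 and 0 adjusted over the list alone).

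Inflammatory cytokine and chemokine genes were partly higher: 7 of 16 measured members were higher and 0 lower (11 and 1 adjusted over the list alone). Tnf rose from 1.03 ± 1.09 to 9.89 ± 2.92 CPM, Cxcl10 from 1.58 ± 0.873 to 10.9 ± 2.48 and Ccl12 from 45.6 ± 8.58 to 223 ± 71.9. Of the immediate-early and dissociation genes, 4 of 17 measured members were higher and 0 lower (4 and 0 adjusted over the list alone), with Ier3 at 37.9 ± 11.9 against 10.1 ± 3.68 CPM and Ier2 at 99 ± 47.8 against 35.9 ± 6.72 CPM. Retinal libraries 2 and 4, whose titles carry the letter b, stood above 1 and 3, with Ier2 at 120.3 and 155.4 against 50.02 and 70.29 CPM, Egr1 at 126.9 and 146.1 against 17.99 and 14.38 and Fos at 85.52 and 112.3 against 19.88 and 18.37. Egr1 did not pass the test in all 4 libraries (log2 fold change 1.34) and passed it without the 3 libraries that lack the letter b (2.17). In the lipid and cholesterol list, 5 of 13 measured members were higher and 3 lower (5 and 3 adjusted over the list alone). The fatty acid binding protein gene Fabp5 (6.5 ± 2.44 against 0.306 ± 0.0954 CPM) and Ch25h (1.38 ± 0.753 against 0.18 ± 0.161) rose. The cholesterol exporters Abca1 (108 ± 52.5 against 348 ± 50.0 CPM) and Abcg1 (53.9 ± 7.11 against 236 ± 31.7) and the desaturase gene Scd2 (52.1 ± 9.57 against 164 ± 34.4) fell. In the complement list, 3 of 10 measured members were higher and 0 lower (3 and 0 adjusted over the list alone), with C3 at 3.47 ± 1.3 against 0.152 ± 0.0686 CPM and C4b at 27.3 ± 8.00 against 4.98 ± 1.83 CPM.

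Border and tissue macrophage genes moved both ways: 2 of 17 measured members were higher and 2 lower (5 and 4 adjusted over the list alone). By fry this list was higher on balance (adjusted p = 0.0385). Ms4a7 (17 ± 3.08 against 0.438 ± 0.485 CPM) and Pf4 (2.1 ± 0.93 against 0.166 ± 0.0895 CPM) were higher, and Mrc1 (9.31 ± 3.07 against 19 ± 6.71 CPM) and Ccl24 (3.31 ± 0.736 against 8.05 ± 2.02 CPM) were lower. Among classical monocyte genes, 2 of 14 measured members were higher and 1 lower (2 and 1 adjusted over the list alone), with Clec4e at 2.31 ± 2.03 against 0.0429 ± 0.0857 CPM and the chemokine receptor Ccr2 at 0.718 ± 0.255 against 5.2 ± 1.38 CPM. Of the myeloid transcription factors, 1 of 19 measured members were higher and 0 lower (1 and 0 adjusted over the list alone), the exception being Klf2 (56.1 ± 14.3 against 8.48 ± 2.87 CPM). In the TGF-beta pathway, 0 of 11 measured members were higher and 1 lower (0 and 2 adjusted over the list alone); Tgfbr1 had 1641 ± 493 against 2778 ± 451 CPM, a call that ended without brain replicate 3 (log2 fold change -0.71). In matrix remodelling and repair, 0 of 15 measured members were higher and 1 lower (1 and 1 adjusted over the list alone); Tgm2 had 42 ± 13.4 against 86.1 ± 8.27 CPM. In the lysosome and phagocytosis list, 1 of 13 measured members were higher and 2 lower (3 and 3 adjusted over the list alone), but 3 were higher and 1 lower with total counts only. Mertk, a receptor for dying cells, fell from 1057 ± 49 to 584 ± 115 CPM. Fry's adjusted p was 0.324 for classical monocyte genes, 0.208 for myeloid transcription factors and 0.16 for immediate-early and dissociation genes.

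Photoreceptor transcripts made up the largest increases. Among the genes with the largest log2 fold changes were Gnat1, Prph2, Rp1, Rbp3, Pdc and Rorb, known from photoreceptors or other retinal cells. Gnat1 was at least 9428-fold higher, Prph2 at least 3154-fold, Rp1 at least 2390-fold, Pdc at least 2232-fold, Rbp3 at least 2210-fold and Rorb at least 1960-fold, with no count in any brain library. In the photoreceptor list, 14 of 14 measured members were higher and 0 lower (14 and 0 adjusted over the list alone). Neuronal genes had 5 higher and 0 lower of 7 (7 and 0 adjusted over the list alone), and Müller and astroglia genes had 3 higher and 1 lower of 9 (4 and 1 adjusted over the list alone). Without the genes whose level tracked the photoreceptor transcripts across the retinal libraries, 1352 genes changed between retinal and brain microglia, 815 higher and 537 lower.

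Among called genes with at least 20 CPM in brain microglia and no overlap between libraries, Gpr165, an orphan receptor, had the largest decrease in retinal microglia (6.28 ± 4.44 against 254 ± 89.4 CPM). It was followed by the semaphorin Sema6d (0.668 ± 0.713 against 23.9 ± 7.5) and Slc39a12, a zinc transporter (1.41 ± 0.929 against 35.4 ± 2.77). Next came Tmem44 (2.85 ± 0.557 against 31 ± 7.83 CPM), Jam3 (3.3 ± 2.73 against 30.6 ± 4.61), Arhgap29 (2.8 ± 0.765 against 24.9 ± 4.56), the semaphorin Sema4b (5.92 ± 1.09 against 41.8 ± 8.67) and Angptl7 (3.5 ± 0.884 against 24.5 ± 3.29). Jam3 no longer passed the test without retinal replicate 2 (log2 fold change -2.96), 3 (-3.00) or 4 (-3.23) or without brain replicate 1 (-3.21) or 3 (-3.15). The sort markers Adgre1 and Csf1r were lower in retinal microglia, with log2 fold changes of -0.91 and -0.54. Itgam (-0.68) was lower and Ptprc (0.50) higher, but both calls ended without single libraries, at -0.67 to -0.63 without retinal replicate 4 or brain replicates 1, 3 or 4 for Itgam, and at 0.45 to 0.50 without retinal replicates 1, 2 or 4 or brain replicates 2, 3 or 4 for Ptprc.

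The lane as a term left fewer members called in most of these lists. Of the disease-associated genes 9 of 10 stayed higher (median log2 fold change 2.93, SE 0.30 before and 2.88, SE 0.41 with the term) and of the MHC class II genes 4 of 4 (3.23, SE 0.36 and 2.90, SE 0.48). For interferon response genes 10 of 16 stayed higher (1.55, SE 0.24 and 1.87, SE 0.33), and for cell cycle genes 8 of 13 (3.52, SE 0.54 and 2.99, SE 0.71). Inflammatory genes kept 5 of 7, lipid and cholesterol genes 3 of 5 higher and 1 of 3 lower, homeostatic microglia genes 3 of 6 lower and photoreceptor genes 4 of 14. None of the 4 immediate-early, 5 neuronal or 3 higher Müller and astroglia genes stayed called, nor did the 3 changed lysosome and phagocytosis genes. Genes named above whose calls ended included Gpr165 (-3.62), Tmem44 (-0.97), Jam3 (-3.64), Upk1b (-2.56), Crybb1 (-1.37), Cd86 (-0.89), Mertk (-0.92), Tgfbr1 (-0.82), Abca1 (-2.06), Scd2 (-1.73), Ank (-0.95), Adgre1 (-0.70) and Itgam (-0.92). Calls of higher genes also ended for Ch25h (2.53), Ifi44 (3.49), Mx1 (1.82), Ier2 (1.37), Ier3 (1.29), Prph2 (11.13), Rp1 (18.10), Rbp3 (13.98), Pdc (13.92) and Rorb (11.17). Rbp3 and Pdc had no count in any cornea or bone marrow library, from which the term was estimated, and kept their log2 fold changes. Those of Prph2 (14.44 before), Rp1 (13.98) and Rorb (13.64) moved. A call that ended is therefore not by itself a sign that the lane made the difference.

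**Figure D3:**
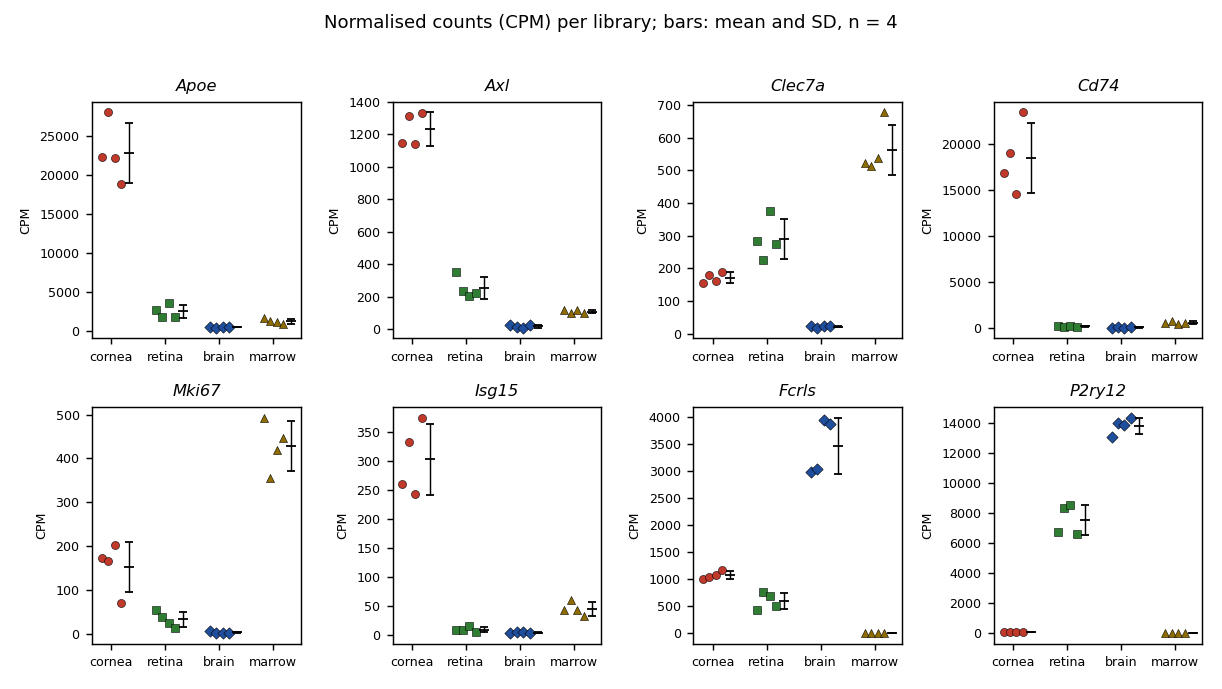
CPM of Apoe, Axl, Clec7a, Cd74, Mki67, Isg15, Fcrls and P2ry12 in each library of the 4 populations, with bars for mean and SD (n = 4). The 4 retinal libraries lie above the 4 brain libraries for Apoe, Axl and Clec7a and under them for Fcrls and P2ry12.

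The comparison of cornea macrophages with retinal microglia sets the resident phagocytes of 2 parts of the eye side by side. Cornea macrophages held the neutrophil-attracting chemokine Cxcl2 at 17524 ± 2436 CPM, against 0.518 ± 0.186 CPM in retinal microglia, and its relatives Cxcl1 and Cxcl3 at 5882 ± 1486 and 1164 ± 356 CPM, against 0.131 ± 0.179 and 0.0223 ± 0.026 CPM. The invariant chain Cd74 of MHC class II stood at 18498 ± 3791 against 149 ± 35.9 CPM, with a log2 fold change of 6.96 (SE 0.26; adjusted p = 9.27e-13). Apoe was also higher in the cornea (22793 ± 3807 against 2531 ± 843 CPM), as were Mrc1, the mannose receptor (1553 ± 101 against 9.31 ± 3.07 CPM), and Spic, a transcription factor of red pulp macrophages (343 ± 18.5 against 0.229 ± 0.286 CPM). Microglial genes were far lower in the cornea, with P2ry12 at 70.2 ± 21.2 against 7527 ± 1012 CPM and Sall1, a transcription factor of microglia, at 0.0997 ± 0.199 against 539.9 ± 134 CPM. Cxcl2 lies on chromosome 5 (90903871 to 90905938), Cd74 on chromosome 18 (60803848 to 60812652) and Spic on chromosome 10 (88674772 to 88685015).

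In this comparison 10399 of 15754 genes changed, 4862 higher and 5537 lower in cornea macrophages, and 8051 at least 2-fold. With total counts only, 2922 were higher and 8489 lower. Libraries of both populations did not overlap for 9310 genes, against 2.86% of genes by chance.

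The genes with the largest increases included Il10, an anti-inflammatory cytokine (at least 9893-fold), the protease inhibitor A2m (at least 12283-fold) and the keratocyte gene Dcn (at least 20597-fold), none of which had a count in retinal libraries. The membrane protein gene Emp1 had 1 count there and a ratio of 100435 (95% counting interval 18025 to 3967017), and Flrt3 likewise, with 61468 (95% counting interval 11032 to 2427903). Of the largest decreases, Pde6g was at least 2466-fold lower in the cornea, Rp1 at least 2560-fold, Pdc at least 2391-fold, Rbp3 at least 2368-fold and Cnga1 at least 1544-fold. These are photoreceptor or retinal genes, unlike Tmem100, which was at least 1642-fold lower in the cornea (101 ± 10.8 CPM in retinal and 121 ± 9.72 CPM in brain microglia).

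Among homeostatic microglia genes, 1 of 19 measured members were higher and 17 lower (1 and 17 adjusted over the list alone) (fry, adjusted p = 6.79e-14). The sugar transporter Slc2a5 stood at 0.26 ± 0.436 against 619.7 ± 110.3 CPM, Sall3 at 0.0567 ± 0.113 against 165 ± 26.9 and Nav3 at 0.144 ± 0.219 against 212 ± 72. Fcrls went the other way, with 1070 ± 69.9 CPM in the cornea and 591 ± 153 CPM in the retina. All members of the inflammatory list passed: 16 of 16 measured members were higher and 0 lower (16 and 0 adjusted over the list alone) (fry, adjusted p = 9.31e-13). Ptgs2, the inducible cyclooxygenase, reached 2602 ± 312 against 0.174 ± 0.152 CPM and the interleukin-1 receptor antagonist Il1rn 6579 ± 419.6 against 1.88 ± 1.11 CPM. In the immediate-early and dissociation list, 16 of 17 measured members were higher and 0 lower (16 and 0 adjusted over the list alone). The heat shock genes Hspa1a (7185 ± 1777 against 4.63 ± 2.91 CPM) and Hspa1b (8258 ± 2272 against 5.41 ± 2.7) led this list, followed by Nr4a1 (509.5 ± 84.4 against 2.74 ± 0.358) and Fosb (44.4 ± 12.1 against 0.442 ± 0.484). Jun had 447 ± 101 and 388 ± 142 CPM and did not pass the test.

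Border and tissue macrophage genes were higher in the cornea: 16 of 17 measured members were higher and 0 lower (17 and 0 adjusted over the list alone). Cd36, a scavenger receptor, stood at 1991 ± 357 against 1.77 ± 1.42 CPM, Cbr2 at 178 ± 34.8 against 0.335 ± 0.483 and Pf4 at 881 ± 78.1 against 2.1 ± 0.93; Ccl8 had no count in the retina and was at least 474-fold higher. In the MHC class II list, 8 of 13 measured members were higher and 5 lower (8 and 5 adjusted over the list alone). Cd40 (509 ± 96.2 against 1.24 ± 1.69 CPM), H2-Aa (2785 ± 442 against 26.2 ± 12.4) and H2-Eb1 (1491 ± 374 against 15 ± 5.1) rose. The lower members were H2-Oa (0.488 ± 0.56 against 30.5 ± 7.39 CPM), H2-Ob (10.5 ± 3.7 against 82.8 ± 14.7), H2-DMa (86 ± 18.7 against 242 ± 56.8), H2-DMb1 (110.3 ± 28.7 against 176 ± 39.9) and H2-DMb2 (4.8 ± 1.9 against 13.4 ± 3.37), which encode chains of DM and DO. Interferon response genes had 16 higher and 0 lower of 18 (16 and 0 adjusted over the list alone), led by Rsad2 (922 ± 215 against 12.2 ± 4.77 CPM) and Ifit1 (828 ± 256 against 19.9 ± 2.45). Disease-associated microglia genes split: 10 of 18 measured members were higher and 7 lower (10 and 7 adjusted over the list alone). Lgals3 (4790 ± 605 against 30.9 ± 11.4 CPM), Spp1, which encodes osteopontin (1164 ± 191 against 20.9 ± 9.63), and Igf1 (192 ± 39 against 10.9 ± 3.48) were higher, and Cst7 (4.4 ± 1.9 against 42.2 ± 21.2) and Trem2 (192 ± 13.2 against 984 ± 244) were lower.

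Matrix remodelling and repair genes had 10 higher and 1 lower of 15 (10 and 1 adjusted over the list alone). The collagenase Mmp13 stood at 789 ± 245 against 0.442 ± 0.75 CPM, the urokinase receptor Plaur at 3083 ± 1545 against 28.5 ± 7.42 and Vegfa at 195 ± 94.1 against 2.21 ± 0.956. The inhibitor Timp2 was lower (299 ± 71 against 410 ± 81.6 CPM), but not without cornea replicate 4 (log2 fold change -0.31) or retinal replicate 1 (-0.34) or 3 (-0.43). Lipid and cholesterol genes had 10 higher and 2 lower of 13 (11 and 2 adjusted over the list alone), with the lipid droplet gene Plin2 at 3276 ± 277 against 47.4 ± 6.76 CPM. Myeloid transcription factors had 10 higher and 7 lower of 19 (10 and 7 adjusted over the list alone): Spic, Id3 (84.6 ± 22.3 against 0.349 ± 0.319 CPM) and Nr1h3 (52.7 ± 15.8 against 0.698 ± 0.56) rose, and Batf3 (0.818 ± 0.42 against 22 ± 6.85) and Mef2c (102 ± 14.8 against 651 ± 176) fell. Complement genes had 5 higher and 3 lower of 10 (5 and 3 adjusted over the list alone), with Cfp, or properdin, at 563 ± 120.1 against 1.5 ± 0.656 CPM and C1qa at 644 ± 52.9 against 1765 ± 531. Lysosome and phagocytosis genes had 5 higher and 6 lower of 13 (5 and 6 adjusted over the list alone), with Msr1 at 541 ± 76 against 3.64 ± 2.46 CPM and Itgb5 at 166 ± 14.9 against 2246 ± 283. TGF-beta pathway genes had 4 higher and 5 lower of 11 (4 and 5 adjusted over the list alone). Classical monocyte genes had 9 higher and 0 lower of 14 (10 and 0 adjusted over the list alone). Dendritic cell genes had 5 higher and 2 lower of 8 (5 and 2 adjusted over the list alone) and lymphocyte and NK genes 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone). Cell cycle genes had 5 higher and 3 lower of 16 (5 and 3 adjusted over the list alone), which turned to 3 higher and 8 lower with total counts only. Mitochondrial transcripts had 4 higher and 0 lower of 9 (4 and 0 adjusted over the list alone), and 0 higher and 1 lower with total counts only.

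Markers of surrounding tissue differed in the same comparison. In the corneal epithelium list, 9 of 10 measured members were higher and 0 lower (9 and 0 adjusted over the list alone), and in the stromal keratocyte and fibroblast list, 9 of 9 measured members were higher and 0 lower (9 and 0 adjusted over the list alone). Krt12 had 195 ± 193 CPM and Krt5 75.5 ± 92 CPM in the cornea, and Lum, the keratocyte proteoglycan lumican, 204 ± 56.1 CPM. Photoreceptor genes had 0 higher and 14 lower of 14 (0 and 14 adjusted over the list alone). Neuronal genes had 0 higher and 5 lower of 7 (0 and 5 adjusted over the list alone), and Müller and astroglia genes 0 higher and 4 lower of 9 (0 and 4 adjusted over the list alone). Oligodendrocyte genes had 1 higher and 2 lower of 5 (1 and 3 adjusted over the list alone). Endothelial genes had 1 higher and 1 lower of 6 (1 and 1 adjusted over the list alone), and neutrophil and granulocyte precursor genes 1 higher and 0 lower of 11 (0 and 0 adjusted over the list alone). The only measured member was not past the threshold among pigmented cell genes (Pmel, 0.657 ± 0.393 against 0.62 ± 0.637 CPM) and was higher among mast cell and basophil genes (Kit, 2.27 ± 2.04 against 0.0934 ± 0.138 CPM). Cornea library 4 was alone of its group in lane 3, and within lane 2, 9694 genes changed.

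Cornea macrophages and brain microglia were compared to contrast the cornea population with microglia outside the eye. Cornea macrophages held Ptgs2 at 2602 ± 312 CPM with no count in brain microglia (at least 38602-fold), and the growth factor Areg at 301 ± 39.8 CPM (at least 4610-fold). Irg1, the source of itaconate, was at least 15564-fold higher, and Cxcl3 at least 16882-fold. Brain microglia held Sall1 at 688 ± 66.2 CPM against 0.0997 ± 0.199 CPM in the cornea, and Slc2a5 at 998 ± 96.6 against 0.26 ± 0.436 CPM. P2ry12 stood at 70.2 ± 21.2 against 13785 ± 519 CPM, a log2 fold change of -7.62 (SE 0.25; adjusted p = 1.44e-13). The test called 10526 genes changed, 5318 higher and 5208 lower in the cornea, and 8264 at least 2-fold. With total counts only, 3566 were higher and 7609 lower. Libraries did not overlap for 9826 genes, against 2.86% of genes by chance.

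Further genes with the largest increases were Ahnak (at least 12797-fold), Flrt3 (at least 12141-fold), Aldh3a1, an aldehyde dehydrogenase of the corneal epithelium (at least 4368-fold), and Emp1, with 1 count in brain libraries and a ratio of 59513 (95% counting interval 10681 to 2350682). The largest decreases, with no count in the cornea, were those of Tmem100 (at least 1975-fold), Asap3 (at least 936-fold), Eva1a (at least 513-fold), Adamts16 (at least 511-fold) and Hspb3 (at least 367-fold). Sall3 had 2 counts in the cornea and a brain to cornea ratio of 4181 (95% counting interval 1157 to 34527). Homeostatic microglia genes had 0 higher and 18 lower of 19 (0 and 18 adjusted over the list alone), inflammatory genes 16 higher and 0 lower of 16 (16 and 0 adjusted over the list alone). Immediate-early and dissociation genes had 16 higher and 0 lower of 17 (16 and 0 adjusted over the list alone) and interferon response genes 17 higher and 0 lower of 18 (17 and 0 adjusted over the list alone). Rsad2 stood at 922 ± 215 against 2.05 ± 1.58 CPM and Ifit1 at 828 ± 256 against 7.22 ± 2.55 CPM. Border and tissue macrophage genes had 16 higher and 0 lower of 17 (16 and 0 adjusted over the list alone), among them Cd163, a haemoglobin scavenger receptor (at least 2594-fold), Pf4 (881 ± 78.1 against 0.166 ± 0.0895 CPM) and Ms4a7 (1508 ± 63.9 against 0.438 ± 0.485). Disease-associated microglia genes had 11 higher and 4 lower of 18 (11 and 4 adjusted over the list alone), with Lgals3 at 4790 ± 605 against 2.69 ± 0.811 CPM and Trem2, among the lower ones, at 192 ± 13.2 against 963 ± 101.

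MHC class II genes had 8 higher and 4 lower of 13 (8 and 4 adjusted over the list alone), with Cd40 at 509 ± 96.2 against 0.18 ± 0.215 CPM. Beside them, dendritic cell genes had 6 higher and 1 lower of 8 (6 and 1 adjusted over the list alone) and classical monocyte genes 11 higher and 0 lower of 14 (11 and 0 adjusted over the list alone). Cell cycle genes had 14 higher and 1 lower of 16 (14 and 1 adjusted over the list alone); Mki67, the Ki-67 gene, stood at 153 ± 57.4 against 3.01 ± 1.5 CPM and the lower member Tyms at 4.64 ± 2.26 against 11.8 ± 2.83. Matrix genes had 11 higher and 1 lower of 15 (12 and 1 adjusted over the list alone), lipid and cholesterol genes 10 higher and 3 lower of 13 (10 and 3 adjusted over the list alone). Transcription factors had 11 higher and 6 lower of 19 (11 and 7 adjusted over the list alone). Complement genes had 6 higher and 3 lower of 10 (6 and 3 adjusted over the list alone), and TGF-beta pathway genes 5 higher and 6 lower of 11 (5 and 6 adjusted over the list alone). Spic had 1 count in brain libraries and a ratio of 15680 (95% counting interval 2814 to 619374). Corneal epithelium genes had 9 higher and 0 lower of 10 (9 and 0 adjusted over the list alone) and stromal genes 9 higher and 0 lower of 9 (9 and 0 adjusted over the list alone). Müller and astroglia genes had 4 higher and 2 lower of 9 (4 and 2 adjusted over the list alone), and 1 higher and 4 lower with total counts only. Erythroid genes had 0 higher and 4 lower of 7 (0 and 4 adjusted over the list alone), with Hba-a2 at 0 against 2.45 ± 4.39 CPM. The call of Hba-a2 ended without any 1 cornea library (log2 fold changes of -8.11 to -8.06) and without brain replicate 3 (-4.95).

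The comparison of cornea macrophages with bone marrow monocytes contrasts a tissue population with monocytes of the bone marrow. Cornea macrophages held Il1a at 1755 ± 334 CPM, where monocytes had 2 counts over 4 libraries, a ratio of 49915 (95% counting interval 13817 to 412172). Cxcl1 (at least 108218-fold), Cxcl3 (at least 21286-fold) and Il10 (at least 7391-fold) had no count in monocytes. Monocytes held the chitinase-like gene Chil3 at 5573 ± 1303 CPM against 0.557 ± 0.457 CPM in the cornea, and the chemokine receptor Ccr2 (chromosome 9, 124101950 to 124113557) at 2688 ± 463 against 54.6 ± 8.81 CPM. The log2 fold change of Ccr2 was -5.62 (SE 0.23; adjusted p = 2.13e-12). In total 9980 genes changed, 5078 higher and 4902 lower in the cornea, and 7606 at least 2-fold. With total counts only, 3503 were higher and 7532 lower. Libraries did not overlap for 9126 genes, against 2.86% of genes by chance.

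Other leading increases were Flrt3 (at least 15308-fold), Dcn (at least 15388-fold), A2m (at least 9177-fold) and Areg (at least 5813-fold). The leading decreases were those of the myeloperoxidase gene Mpo (at least 6811-fold), the neutrophil elastase gene Elane (at least 2749-fold), the haemoglobin gene Hba-a2 (at least 3307-fold) and Serpinb10 (at least 1495-fold). Haptoglobin (Hp) had 1 count in the cornea and a monocyte to cornea ratio of 52948 (95% counting interval 9503 to 2091363), and Cd177 had 3 counts and a ratio of 9980 (95% counting interval 3415 to 48394). Ly6c2 stood at 0.182 ± 0.294 against 2464 ± 141 CPM. Classical monocyte genes had 1 higher and 13 lower of 14 (1 and 13 adjusted over the list alone); the higher member, Clec4e, stood at 1648 ± 138 against 25.1 ± 5.12 CPM. Neutrophil and granulocyte precursor genes had 0 higher and 11 lower of 11 (0 and 11 adjusted over the list alone) and erythroid genes 0 higher and 7 lower of 7 (0 and 7 adjusted over the list alone).

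Inflammatory genes had 16 higher and 0 lower of 16 (16 and 0 adjusted over the list alone). Immediate-early and dissociation genes had 15 higher and 0 lower of 17 (15 and 0 adjusted over the list alone) and MHC class II genes 10 higher and 2 lower of 13 (10 and 2 adjusted over the list alone). Dendritic cell genes moved both ways, with 3 higher and 3 lower of 8 (3 and 3 adjusted over the list alone). Cd74 stood at 18498 ± 3791 against 577 ± 116 CPM, and among the lower class II members H2-DMa stood at 86 ± 18.7 against 189.5 ± 12.9 CPM. Border and tissue macrophage genes had 16 higher and 1 lower of 17 (16 and 1 adjusted over the list alone), with Dab2 at 2049 ± 92.1 against 1.36 ± 0.875 CPM and the lower member F13a1, a coagulation factor gene, at 771 ± 273 against 6386 ± 1190 CPM. Interferon response genes moved both ways, with 5 higher and 7 lower of 18 (5 and 7 adjusted over the list alone): Rsad2 (922 ± 215 against 117 ± 7.62 CPM) and Isg15 (303 ± 61.1 against 45.1 ± 11.3) were higher, and Zbp1 (33.5 ± 8.72 against 156 ± 22.3) was lower. Cell cycle genes had 1 higher and 15 lower of 16 (1 and 15 adjusted over the list alone), with Plk1 at 1.5 ± 0.899 against 53.7 ± 4.76 CPM and the exception Pcna at 76.1 ± 5.43 against 29.3 ± 9.74. Homeostatic microglia genes had 13 higher and 2 lower of 19 (13 and 2 adjusted over the list alone), complement genes 8 higher and 2 lower of 10 (8 and 2 adjusted over the list alone) and lysosome and phagocytosis genes 10 higher and 2 lower of 13 (10 and 2 adjusted over the list alone). The 3 complement C1q genes were among the higher ones, with C1qb at 4093 ± 240.3 against 8.82 ± 10.1 CPM. Corneal epithelium genes had 10 higher and 0 lower of 10 (10 and 0 adjusted over the list alone) and stromal genes 9 higher and 0 lower of 9 (9 and 0 adjusted over the list alone). Mitochondrial transcripts had 2 higher and 0 lower of 9 (1 and 0 adjusted over the list alone), and 0 higher and 3 lower with total counts only.

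**Figure D4:**
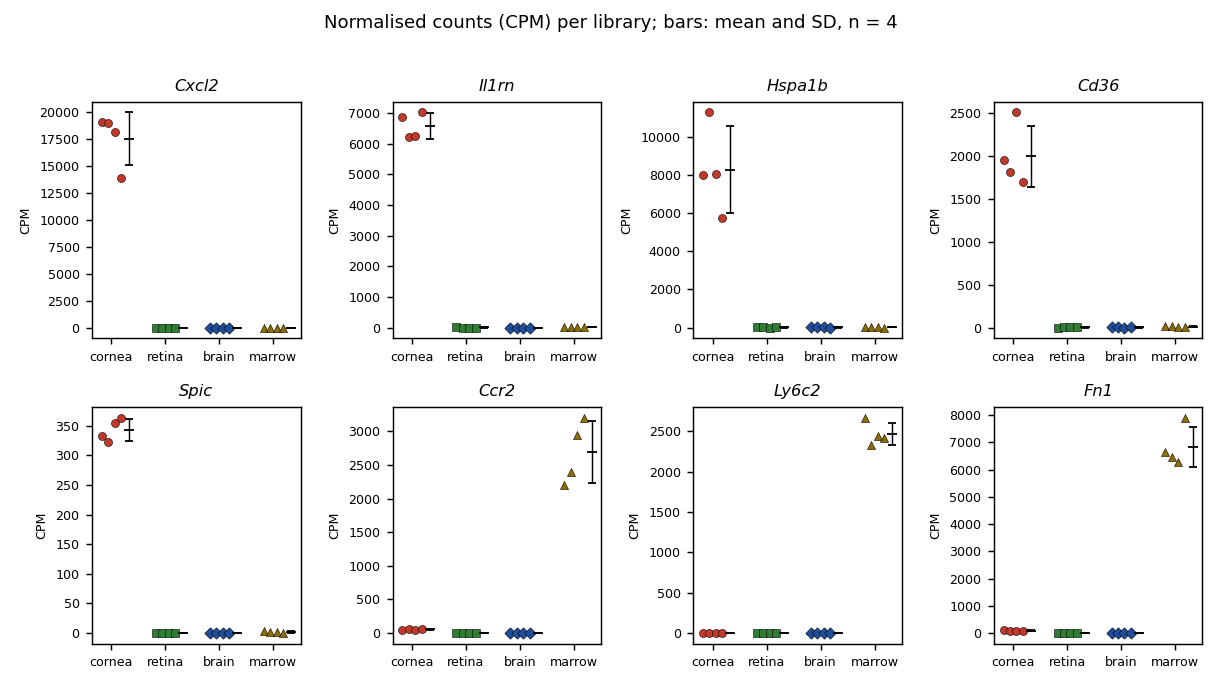
CPM of Cxcl2, Il1rn, Hspa1b, Cd36, Spic, Ccr2, Ly6c2 and Fn1 in each library of the 4 populations, with bars for mean and SD (n = 4). The first 5 genes are highest in all 4 cornea libraries and the last 3 in all 4 bone marrow libraries.

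Retinal microglia and bone marrow monocytes were compared in the same way. Retinal microglia held Sall1 at 539.9 ± 134 CPM, where monocytes had 1 count, a ratio of 30433 (95% counting interval 5462 to 1202068), and P2ry12 at 7527 ± 1012 against 6.97 ± 1.57 CPM. Lrrc3 (at least 6422-fold), Tspan7 (at least 3289-fold) and the protease inhibitor Spint1 (at least 3130-fold) had no count in monocytes. Monocytes held more Chil3 (5573 ± 1303 against 0.326 ± 0.625 CPM) and more fibronectin, Fn1 (6817 ± 732 against 0.984 ± 1.09 CPM). Ccr2 stood at 0.718 ± 0.255 against 2688 ± 463 CPM, a log2 fold change of -11.87 (SE 0.31; adjusted p = 2.05e-14). In all, 9338 genes changed, 5069 higher and 4269 lower in retinal microglia, and 6710 at least 2-fold. With the lane as a term, 7506 genes changed, 3685 higher and 3821 lower. Libraries did not overlap for 8701 genes, against 2.86% of genes by chance.

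The photoreceptor genes Prph2 (at least 3977-fold), Pde6g (at least 2902-fold), Rbp3 (at least 2787-fold) and Gnat1, with 1 count in monocytes and a ratio of 35661 (95% counting interval 6400 to 1408545), were also among the largest increases. The largest decreases were those of Cd177 (at least 15719-fold), Mpo (at least 10727-fold), lactoferrin or Ltf (at least 9625-fold), Hba-a1 (at least 7127-fold), Hbb-bt (at least 7002-fold) and Nxpe4 (at least 4608-fold). Hbb-bs had 1 count in retinal libraries and a monocyte to retina ratio of 46887 (95% counting interval 8415 to 1851991). Homeostatic microglia genes had 19 higher and 0 lower of 19 (19 and 0 adjusted over the list alone). Classical monocyte genes had 0 higher and 14 lower of 14 (0 and 14 adjusted over the list alone). Interferon response genes had 0 higher and 17 lower of 18 (0 and 17 adjusted over the list alone) and cell cycle genes 0 higher and 14 lower of 16 (0 and 15 adjusted over the list alone). Markers of other bone marrow cells moved with them: neutrophil and granulocyte precursor genes had 0 higher and 11 lower of 11 (0 and 11 adjusted over the list alone) and erythroid genes 0 higher and 7 lower of 7 (0 and 7 adjusted over the list alone). Photoreceptor genes had 14 higher and 0 lower of 14 (14 and 0 adjusted over the list alone), and dendritic cell genes 2 higher and 3 lower of 8 (2 and 3 adjusted over the list alone). Müller and astroglia genes had 8 higher and 0 lower of 9 (8 and 0 adjusted over the list alone) and neuronal genes 6 higher and 0 lower of 7 (6 and 0). Mitochondrial transcripts had 0 higher and 3 lower of 9 (0 and 3 adjusted over the list alone). Their sum was 17140 CPM in monocyte library 4, against 5932 to 6898 CPM in the other monocyte libraries. Complement genes had 7 higher and 3 lower of 10 (7 and 3 adjusted over the list alone), with C1qc at 5078 ± 1206 against 5.02 ± 5.15 CPM and C3, one of the lower members, at 3.47 ± 1.3 against 1771 ± 125. Disease-associated microglia genes had 12 higher and 5 lower of 18 (12 and 5 adjusted over the list alone), with Cd9 at 1668 ± 513 against 10.7 ± 6.21 CPM and Lgals3 at 30.9 ± 11.4 against 1462 ± 105. Border and tissue macrophage genes had 7 higher and 9 lower of 17 (7 and 9 adjusted over the list alone); with the DESeq2 Wald test, 7 were higher and 5 lower. Inflammatory genes had 10 higher and 2 lower of 16 (10 and 2 adjusted over the list alone), and lysosome and phagocytosis genes 10 higher and 2 lower of 13 (10 and 2 adjusted over the list alone).

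Brain microglia were set against the same monocytes. Brain microglia held Tspan7 (at least 4570-fold), Lrrc3 (at least 5737-fold) and the junction gene Tjp1 (at least 3384-fold) with no count in monocytes. Slc2a5 had 2 counts in monocytes and a ratio of 28574 (95% counting interval 7910 to 235954), and Sall1 had 1 and a ratio of 39546 (95% counting interval 7097 to 1562034). Monocytes held Fn1 at 6817 ± 732 against 0.302 ± 0.296 CPM. P2ry12 stood at 13785 ± 519 against 6.97 ± 1.57 CPM, a log2 fold change of 10.97 (SE 0.28; adjusted p = 1.66e-14). The test called 8817 genes changed, 4494 higher and 4323 lower in brain microglia, and 6378 at least 2-fold. Libraries did not overlap for 8926 genes, against 2.86% of genes by chance.

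Further large increases were those of Sgce (at least 3153-fold), Spint1 (at least 2727-fold) and Ecscr, with 1 count in monocytes and a ratio of 23827 (95% counting interval 4276 to 941174). Further large decreases, with no count in brain microglia, were those of Ahnak (at least 21902-fold), the neutrophil collagenase Mmp8 (at least 4521-fold), Atp8b4 (at least 4147-fold), coagulation factor F10 (at least 2862-fold), Gda (at least 2554-fold) and Arhgef37 (at least 2409-fold). Homeostatic microglia genes had 19 higher and 0 lower of 19 (19 and 0 adjusted over the list alone). Classical monocyte genes had 0 higher and 14 lower of 14 (0 and 14 adjusted over the list alone). Interferon response genes had 0 higher and 18 lower of 18 (0 and 18 adjusted over the list alone) and cell cycle genes 0 higher and 15 lower of 16 (0 and 15 adjusted over the list alone). Here too, neutrophil and granulocyte precursor genes had 0 higher and 11 lower of 11 (0 and 11 adjusted over the list alone) and erythroid genes 0 higher and 7 lower of 7 (0 and 7 adjusted over the list alone). Dendritic cell genes had 2 higher and 4 lower of 8 (2 and 4 adjusted over the list alone). Müller and astroglia genes had 6 higher and 0 lower of 9 (6 and 0 adjusted over the list alone) and mitochondrial transcripts 1 higher and 4 lower of 9 (1 and 4). For the mitochondrial transcripts, the monocyte level again included library 4, which stood above the other monocyte libraries. MHC class II genes moved both ways, with 5 higher and 6 lower of 13 (5 and 6 adjusted over the list alone): Cd40 (0.18 ± 0.215 against 38.3 ± 2.46 CPM) and H2-Aa (1.37 ± 1.22 against 61.7 ± 20.9) were lower, and H2-Oa (31.5 ± 5.58 against 0.825 ± 0.317) and H2-Ob (58.4 ± 4.8 against 1.8 ± 0.95) higher. Disease-associated microglia genes had 7 higher and 8 lower of 18 (7 and 8 adjusted over the list alone), with Lgals3 at 2.69 ± 0.811 against 1462 ± 105 CPM and Cd9 at 906 ± 52.5 against 10.7 ± 6.21. TGF-beta pathway genes had 7 higher and 1 lower of 11 (8 and 1 adjusted over the list alone), with the receptor gene Tgfbr1 at 2778 ± 451 against 78.9 ± 3.85 CPM. Within lane 3, 8600 genes changed between brain microglia and monocytes.

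**Figure D5:**
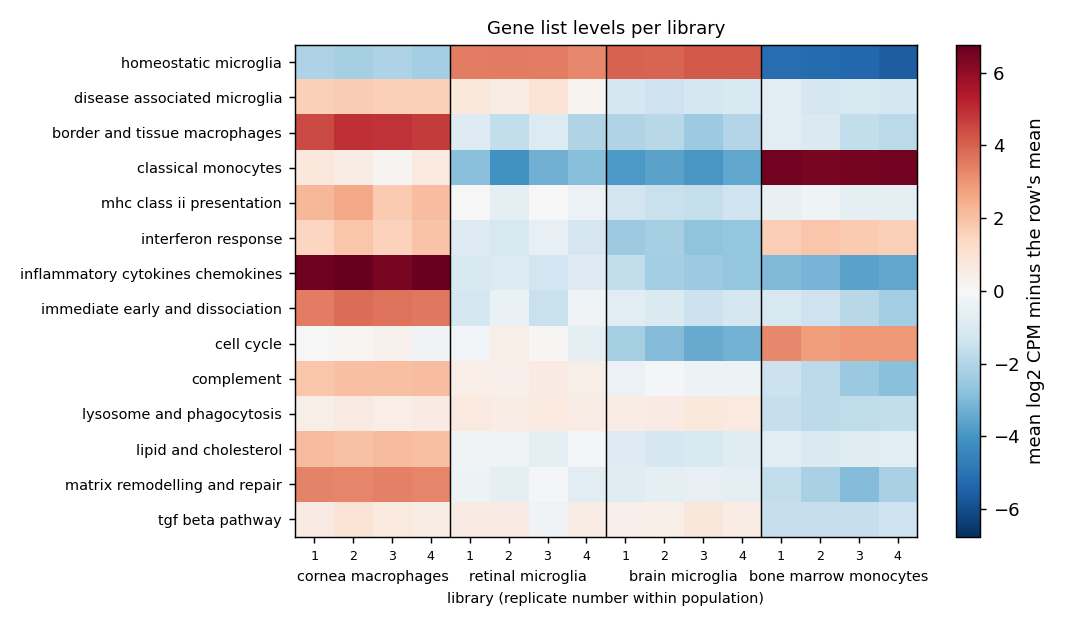
Mean log2 CPM of 14 gene lists in each of the 16 libraries, as the difference from the mean of the same list over all libraries (colour scale), with 4 columns per population. Homeostatic microglia genes are highest in retinal and brain microglia, inflammatory genes in cornea macrophages and classical monocyte genes in bone marrow monocytes.

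Genes at least 2-fold higher in 1 population than in each of the other 3 were counted as its signature. Cornea macrophages had 2194 such genes, monocytes 1147, retinal microglia 212 and brain microglia 63. The cornea signature was led by Flrt3, the chemokines Cxcl3, Cxcl1 and Cxcl2, Ptgs2 and Areg. Their levels lay between 301 ± 39.8 CPM (Areg) and 17524 ± 2436 CPM (Cxcl2). Enzyme digestion, described for the cornea and not for the retina, could raise the inflammatory genes among them and cannot be told apart from the tissue. Cornea libraries also held 2083 to 3543 CPM of epithelial and stromal marker transcripts. Without mitochondrial, haemoglobin, photoreceptor and corneal marker genes, this signature held 2157 genes. Other genes that track the corneal markers were not left out, so it may include transcripts of other corneal cells. The monocyte signature was led by Elane, Cd177, Ly6c2, Hp, Chil3 and Mpo, from 153 ± 57.6 CPM (Elane) to 5573 ± 1303 CPM (Chil3). Among the leading genes of the retinal signature were the photoreceptor genes Rbp3, Pdc, Cnga1 and Gngt1, with 142 ± 118 CPM (Rbp3) and 86.6 ± 51.5 CPM (Gngt1). The brain signature was led by Gpr165 (254 ± 89.4 CPM), Tmem44, Slc39a12, Jam3, Gprasp2 and Khdrbs3. The RNA-binding protein gene Khdrbs3 had 72.2 ± 8.69 CPM in brain and 14.8 ± 4.08 CPM in retinal microglia, the next population, and Gprasp2 had 34.2 ± 6.89 and 6.79 ± 3.57 CPM. The cornea signature held 1400 genes with total counts only, and the brain signature 116 with limma-voom. The retinal signature held 104 genes under the stricter filter of 5 CPM in 4 libraries, fell to 72 genes without the genes that tracked photoreceptor transcripts, and to 47 with the lane as a term. With that term the brain signature held 71 genes, of which 18 were among the 63, and 34 of the 47 retinal genes were among the 212.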

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

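The test for single libraries that stand apart from their group was chosen before the result was seen. In 12 of 172 groups of 4 libraries, 1 library lay so far from the other 3 that its gap passed Dixon's 95% critical value, which chance alone passes in about 5% of groups. Bone marrow monocyte library 4 was the 1 apart in 5 of them. Its summed mitochondrial transcripts reached 17140 CPM, against 5932 to 6898 CPM in the other 3. Its border and tissue macrophage genes summed to 8217 CPM (others 5699 to 5999), its complement genes to 2495 CPM (others 2232 to 2270) and its lipid and cholesterol genes to 1437 CPM (others 1153 to 1196). Serpinb10 stood at 145 CPM in this library and at 71.4 to 81.3 CPM in the others.

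Among the other populations, Müller and astroglia genes summed to 288 CPM in retinal library 4 (others 227 to 232) and to 32.3 CPM in monocyte library 1 (others 20.2 to 21.8). Interferon response genes summed to 297 CPM in brain library 2 (others 265 to 268). The only measured sex-linked gene, Xist, had 260.0 CPM in brain library 3 (others 142 to 154). A2m had 767 CPM in cornea library 3 (others 348 to 405), Cxcl3 had 636 CPM in cornea library 4 (others 1283 to 1411), and Adamts16 had 39.1 CPM in brain library 1 (others 27.7 to 29.6).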

How the results depend on the processing

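Alternatives chosen after seeing the data were the lane as a term, fits within 1 lane, and leaving out genes that tracked photoreceptor transcripts. Over the 6 comparisons, 118 of 120 counts of changed genes under an alternative stayed within 1.5 times the reported count. The 2 exceptions were both for retinal against brain microglia: 1008 genes with at least 2-fold changes required and 463 with the lane as a term. The first follows from the stricter criterion, and for the second the cause was not tested. Leaving out 1 library at a time gave 1140 to 1657 genes for this comparison. Counts of changed genes take no account of direction. With total counts only, 124, 32 and 42 genes called in both fits had the opposite direction for cornea against retina, brain and bone marrow. For cornea against retina the share of higher genes fell from 46.8% to 25.6%. Of 7440 counts of list members called higher or lower, 524 moved. Of 108 signature sizes, 8 moved by more than 1.5 times. With total counts only, the cornea signature held 1400 genes, and with a log2 fold change of at least 2 it held 1333, the brain signature 25 and the monocyte signature 567, by the stricter criterion. The brain signature held 116 genes with limma-voom, where the cause was not tested. The retinal signature held 104 genes under the stricter filter, with fewer genes tested. Without the genes that tracked photoreceptor transcripts it held 72 genes, 63 of them among the reported 212, though 14352 of 15754 genes were still tested. That setting left out the signature genes that themselves tracked these transcripts. With the lane as a term the retinal signature held 47 genes, where the cause was not tested. The size of the brain signature hides a change of members with that term: of its 71 genes, 18 were among the reported 63, and the cause was not tested.

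Of 17297 log2 fold changes of named genes and list members under an alternative, 16801 kept their direction and side of the threshold, 401 no longer passed it, 88 newly passed it and 7 reversed. With total counts only, the reversed ones were Npc2 (-0.26), mt-Nd4 (-0.18) and mt-Co2 (-0.19) for cornea against retina, Smad2 (-0.20) for cornea against brain, and Rtp4 (-0.18) and mt-Nd2 (-0.02) for cornea against bone marrow, which follows from the shift of all genes under that setting. With the lane as a term, Adamts1 reversed to -6.84 for retinal against brain microglia; the cause was not tested. The share of higher genes among changed genes moved by 11 points at most under settings other than the scaling and the fold criterion, from 65.9% to 54.9% with limma-voom for retinal against brain microglia. With a block for the ranges shared by the titles of brain and bone marrow libraries, 8858 genes changed, against 8942 without the block on the same 8 libraries; the titles state no pairing. Residuals of libraries with the same range had correlations across genes of -0.01 and 0.033, within the -0.027 to 0.039 of the other pairs of libraries. Depth limits the lowest levels: a count of 0 in 4 libraries gives a lower bound only. In simulated data with few changed genes, none of them at the lowest levels, 32.8% to 56.7% of 2-fold changes were recovered.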

Other observations

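All tests of explanations here were chosen after the result was seen, except the splits of the libraries and 2 others. These 2 were the slope on the epithelial and stromal sums together and the ratio of haemoglobin to early granulocyte genes. Slopes on the epithelial or the stromal sum alone were not among the tests set beforehand.

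Several genes known from other cell types had levels that no comparison above described, and they were chosen after their values were seen. Cd79b, a B cell receptor component, had 56.6 ± 16.4 CPM in retinal and 61.7 ± 12.4 CPM in brain microglia, against 26.3 ± 3.18 CPM in monocytes and 2.77 ± 0.334 CPM in cornea macrophages. The myelin gene Mbp was highest in monocytes (274 ± 8.04 CPM), with 40.5 ± 4.57 and 37 ± 2.04 CPM in retinal and brain microglia. Slc1a3, a glutamate transporter of astroglia, had 262 ± 11 CPM in brain and 86.5 ± 8.47 CPM in retinal microglia, and Pecam1, an endothelial adhesion gene, 41.4 ± 5.3 and 7.65 ± 2.56 CPM. Xcr1 and Cd4 were higher in cornea macrophages (42.2 ± 5.00 and 48.2 ± 15.3 CPM) than in the other populations, where neither exceeded 1.01 ± 1.00 CPM. Xist, the only measured sex-linked gene, was lower in monocytes (77.7 ± 2.52 CPM) than in cornea macrophages (154 ± 80.7 CPM), retinal microglia (191 ± 120.3 CPM) or brain microglia (176 ± 56.8 CPM). Each of these calls of Xist depended on single libraries: against the cornea it ended without cornea replicate 1 (log2 fold change 0.69) or 3 (0.78) or any 1 monocyte library (0.95 to 0.99). Against the retina it ended without retinal replicate 1 (0.80), and against the brain without brain replicate 3 (0.94).

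Blood cell transcripts in brain microglia varied between libraries. Neutrophil and granulocyte precursor genes summed to 19.5 CPM in brain library 2, and erythroid genes to 47.7 CPM in brain library 3. The haemoglobin genes Hbb-bs, Hbb-bt and Hba-a1 passed the test as lower in retinal than in brain microglia. None of these calls held without brain replicate 3 (log2 fold changes of -4.23, -5.23 and -5.10), nor without any 1 retinal library (-9.06 to -7.34 for Hbb-bs, -8.24 to -8.15 for Hbb-bt and -8.23 to -8.14 for Hba-a1).

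A first pattern was that 43 genes of the disease-associated, interferon, MHC class II and cell cycle lists were higher in retinal than in brain microglia, with a median log2 fold change of 2.69 (median SE 0.33). RNA carried into the sort with that of photoreceptors would make these genes follow the photoreceptor sum across the 4 retinal libraries at a median slope of 0.85, but their median slope was -0.2 (quartiles -0.38 to -0.08), which argues against it. With the lane as a term, 31 of the 43 stayed called and the other calls ended while errors widened, with a median of 2.63 and a median SE of 0.46. The bound set first for this test, 0.9 of the genes, was missed, so the test does not decide on the lane. The median stayed near its value without the term, but the criterion on the median was added after that result. The term assumes an effect alike in all populations, and only 1 cornea library was in lane 3 and 1 bone marrow library in lane 2. Border macrophages, which the CD45+CD11b+ gate would keep, may contribute: the 13 border genes with at least 1 CPM had a median log2 fold change of 1.09, yet Mrc1 (9.31 ± 3.07 against 19 ± 6.71 CPM) and Ccl24 were lower while Ms4a7 (17 ± 3.08 against 0.438 ± 0.485 CPM) and Pf4 were higher, which leaves this open. A difference between retina and brain as tissues also stays open and was not tested.

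A second pattern was that 30 genes of the inflammatory and the immediate-early and dissociation lists were higher in cornea macrophages than in each of the other 3 populations. Neutrophils in the cornea sort are argued against, since S100a8, S100a9 and Retnlg summed to at most 3.32 CPM in a cornea library, against 65 to 1500 CPM in monocyte libraries, and the F4/80 and CD64 gate would remove neutrophils. RNA of corneal epithelium or stroma, such as Dcn (774 ± 237 CPM) and Krt12 (195 ± 193 CPM), would need a slope near 1 on its marker sum. Across the 4 cornea libraries the epithelial sum ranged from 260.3 to 1716 CPM. The median slope on it alone, a measure not set beforehand, was -0.04 (quartiles -0.26 to 0.1), which argues against epithelial RNA. The stromal sum ranged only from 1501 to 2819 CPM, and both sums together from 2083 to 3543 CPM. Median slopes were -0.16 (quartiles -0.41 to 0.2) on the stromal sum and -0.37 (quartiles -0.54 to -0.14) on both together. These rest on 4 libraries over a narrow range, so they do not decide on stromal RNA. Enzyme digestion at 37 °C, described for the cornea and not for the retina, could raise such genes and cannot be told apart from the tissue, since no cornea was left undigested and no retina digested. A state of these cells in the cornea itself stays open and was not tested.

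A further pattern was that granulocyte and haemoglobin transcripts varied between bone marrow monocyte libraries, though the CD115 and Ly6C gate would remove most granulocytes and erythroid cells. Haemoglobin genes summed to 2402, 1572, 450 and 351.1 CPM in libraries 1 to 4, late granulocyte genes to 3775, 1733, 323 and 183.5 CPM, and the early genes Mpo, Elane, Prtn3 and Ctsg to 938.1, 453, 455.8 and 583.5 CPM. A single mixed source supplying all of these transcripts would keep their ratios, but the log2 ratio of haemoglobin to early granulocyte genes spanned 2.53, and that to late granulocyte genes 1.59, which argues against such a source. The log2 ratio of any 2 of the early genes spanned at most 0.42. A source added to a level that the sorted monocytes hold themselves was not tested, and no biological explanation was tested.

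Whether any grouping of the libraries would give such counts was tested by refitting the 8 libraries of each comparison under all 35 splits into 4 and 4. For each of the 6 comparisons, 1 of the 35 splits gave as many genes, the real one. For retina against brain, the real split is also that of the lanes. With edgeR, the real splits called 1551 genes (retina against brain), 9426, 9766 and 9124 (cornea against retina, brain and bone marrow), 8853 (retina against bone marrow) and 8942 (brain against bone marrow). All other splits called 0, with at most 1419, 849, 605, 697, 1538 and 764 genes at an unadjusted p under 0.05, against 3668, 9988, 10093, 9582, 9406 and 9287 for the real splits. For the signatures, 1 of 100 splits of the 16 libraries (the real one and 99 drawn) gave a signature as large as the 2194, 212, 63 and 1147 genes found, and the highest of the others was 0. All splits but the real one mix populations, which differ widely except for retinal and brain microglia (mean correlation 0.939). Mixing widens the spread within groups, and shared title numbers leave open whether libraries are exchangeable. A count of 0 in the mixed splits was to be foreseen, so neither test decides on chance.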
